A study of Mus musculus with 12 samples.

How the data were processed

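Gene expression was measured on 12 Illumina mouse BeadArrays, 3 for each of 4 groups of bone marrow cells. Per the labels' protocols, cells of 3-month-old C57BL/6 mice were sorted by flow cytometry, total RNA was extracted with an RNeasy Mini kit, amplified with the Nugen Ovation Pico kit and labelled with biotin through the Ambion MessageAmp kit. The groups were haematopoietic stem cells (HSC, sorted as negative for lineage markers and CD34 and positive for c-Kit, Sca-1 and Slam1) of wild-type (WT) and of KO mice, and committed progenitors (Prog, sorted as negative for lineage markers and Sca-1 and positive for c-Kit) of both genotypes. The labels write the genotype only as KO, and the series title names miR-29a. No probe of miR-29a was found by symbol or synonym, so the loss of the targeted gene was not checked here.

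The deposited signal table holds, per the file headers, the mean bead intensity of each of 45281 probes on each array and a detection p-value against the negative controls of that array. The p-values fall on steps that imply 936 negative controls. The array medians differ, so these intensities had not been normalized between arrays when the authors deposited them. A second deposited table holds log2 values of the same arrays, whose sorted values differ between the 12 arrays by at most 0.000742. The method behind the authors' log2 values is not given in the sources used here. The scanner software, any local background subtraction and the slide of each array are not given in the sources used here either. In the signal table, 23 further columns of per-sample values were not used here.

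The intensities were background corrected and quantile normalized with neqc (offset 16) in limma 3.58.1 under R 4.3.3, with the background inferred from the detection p-values. Across probes, the result correlated with the authors' log2 values at r = 0.995. Probes were named through the Entrez gene ID (29586 probes), an accession (2759) or a synonym (2371) in a table of RefSeq genes of the assembly GRCm38.p6, and 10565 probes kept the symbol of the file. No genome build is named in the files, so no coordinates are given. A probe entered the tests with a detection p-value under 0.05 on at least 3 of the 12 arrays, which kept 20737 probes (45.8%). For each of the 13841 genes the probe with the highest mean level was used. A total of 4481 genes had more than 1 such probe, and where another probe of a named gene moved the opposite way, its value is given beside the gene. Other probes that moved the same way, some by far less, are given only for some genes.

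Each comparison was a contrast of group means in a single limma fit of all 12 arrays (lmFit and eBayes, 8 residual degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Adjusted p-values of genes come from this limma fit unless another source is named, and log2 fold changes are given with their standard errors (SE). The comparisons were KO against WT in HSC and in committed progenitors, HSC against committed progenitors in WT and in KO, and the difference of both KO effects (the interaction). Each array is treated as a replicate. The labels do not say that arrays of a group came from separate mice, so p-values measure only the spread between these samples. A total of 25 gene lists fixed before the data were examined was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The same lists were tested with an estimated correlation and with fry, which asks only whether the genes of a list move on balance one way. Counts "adjusted over the list alone" use the members of a list as the only genes tested. In simulated data with 100 genes changed by 1 and 100 genes changed by 2 on the log2 scale between the HSC groups, the fit of 13841 genes recovered 13% and 74% of them, with 5 false calls among 92. A simulated list of 30 genes shifted by 0.7 was called, and 0 of 24 unchanged lists were. The simulated genes varied independently of each other, so this does not cover false list calls through correlated genes.

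Named genes were chosen by a rule fixed at the same time as the lists. In each comparison of a pair of groups, they are the 10 genes past the threshold with the largest log2 fold change in each direction, completed, where fewer passed, to 5 with genes of the smallest unadjusted p whose groups did not overlap. To these come up to 2 members in each direction of each list described, and always Dnmt3a, Dnmt3b, Tet2, Mcl1, Cdk6, Mpo, Meis1, Mecom and the gate antigens Kit, Ly6a, Slamf1 and Cd34. For the interaction, the 5 genes with the smallest adjusted p in each direction are named. Genes that carry only a clone or locus symbol, and genes not above background in both groups, are counted and not named. A few genes that the rule takes are not reported here. Where the probe used was detected on no array of a group, the fold is a bound, the mean of the brighter group against, per array of the dimmer group, the higher of its own value and the lowest detected signal, and is written as at least N-fold.

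Alternatives covered quantile values without background correction, median scaling, the authors' log2 values, other detection filters, all probes, other variance models, array weights, a fit of only the groups compared, replicate and title numbers as blocks, and leaving out each array in turn. The level of Xist as a covariate was added after seeing the data. A test of miR-29 seed sites in 3' UTRs and a slide block were planned and not run, since transcript sequences and slides were not used here. The figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The number of arrays limits the precision of every value. Exact permutation tests of 3 against 3 arrays cannot give a p below 0.1.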

Results

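The data set holds transcript levels of haematopoietic stem cells, the rare self-renewing cells of the bone marrow, and of the committed progenitors they give rise to, in WT mice and in KO mice of a study whose title names the microRNA miR-29a and the DNA methyltransferase Dnmt3a. Each of the 4 groups had 3 arrays, and n = 3 for every mean and SD given here. The share of probes detected was 40% ± 1.04 (SD) in WT HSC, 37.3% ± 4.96 in KO HSC, 34.4% ± 1.05 in WT committed progenitors and 32.0% ± 2.56 in KO committed progenitors. KO HSC replicate 2 stood lowest among the HSC arrays at 31.6%, with a median signal of 161 against 103 to 116 on the other HSC arrays. The first principal component held 42.4% of the variance and separated HSC from committed progenitors, and the second held 8.22%. The arrays also differed in the level of Xist, the RNA of the inactive X chromosome, which lay at 9.23 to 10 (log2) on WT HSC replicates 1 and 2, KO HSC replicate 1 and WT committed progenitor replicate 2, and at 4.46 to 5.57 on the other 8 arrays. The labels give no sex.

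The comparison of KO with WT HSC asks how gene expression in stem cells differs without the KO gene. Genes of the cell cycle were higher in KO HSC and genes associated with HSC were lower. Of 29 G1/S genes measured, which act in DNA replication and its licensing, 28 had a higher mean in KO HSC, with a mean log2 fold change of 0.76 (camera, adjusted p = 1.47e-12, adjusted p = 0.000978 with an estimated correlation). Of 32 G2/M genes, which act in mitosis, 29 were higher, with a mean of 0.70 (adjusted p = 1.71e-12, 0.00343 with an estimated correlation). HSC-associated genes were lower for 42 of 44 members, with a mean of -0.60 (adjusted p = 2.01e-09, 0.0313 with an estimated correlation), and genes of oxidative phosphorylation were higher for 59 of 67, with a mean of 0.34 (adjusted p = 6.23e-08, 0.0219 with an estimated correlation).

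Among single G1/S genes, 2 rose past the threshold over all genes and 3 when adjusted over the list alone. Gins1, a subunit of the replicative helicase complex, rose by 1.61 ± 0.29 (log2, SE, adjusted p = 0.0333), and Rrm2, the small subunit of ribonucleotide reductase, by 1.52 ± 0.28 (adjusted p = 0.0336), while Chaf1b, a histone chaperone subunit, gave -0.20. No G2/M gene passed over all genes, and 9 rose when adjusted over the list alone. Topoisomerase Top2a gave 1.44 (adjusted p = 0.0804, a second probe gave -0.23) and the centromeric histone Cenpa 1.31 (0.119), against -0.54 for Cdk1 and -0.46 for Hmmr (a second probe gave 0.27). Top2a passed with array weights (adjusted p = 0.045) and Cenpa with the trend and robust variance model (0.0308). No HSC-associated gene passed over all genes and 10 fell when adjusted over the list alone. The angiopoietin receptor Tek gave -1.47 ± 0.33 (adjusted p = 0.0887). It passed without KO HSC replicate 2 (-1.76, adjusted p = 0.0436), without background correction (adjusted p = 0.032) and with array weights (0.0463). Of the 67 oxidative phosphorylation genes none passed either way. The complex I subunit Ndufs8 gave 1.02 and the complex III subunit Uqcrc1 0.81.

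**Figure D1:**
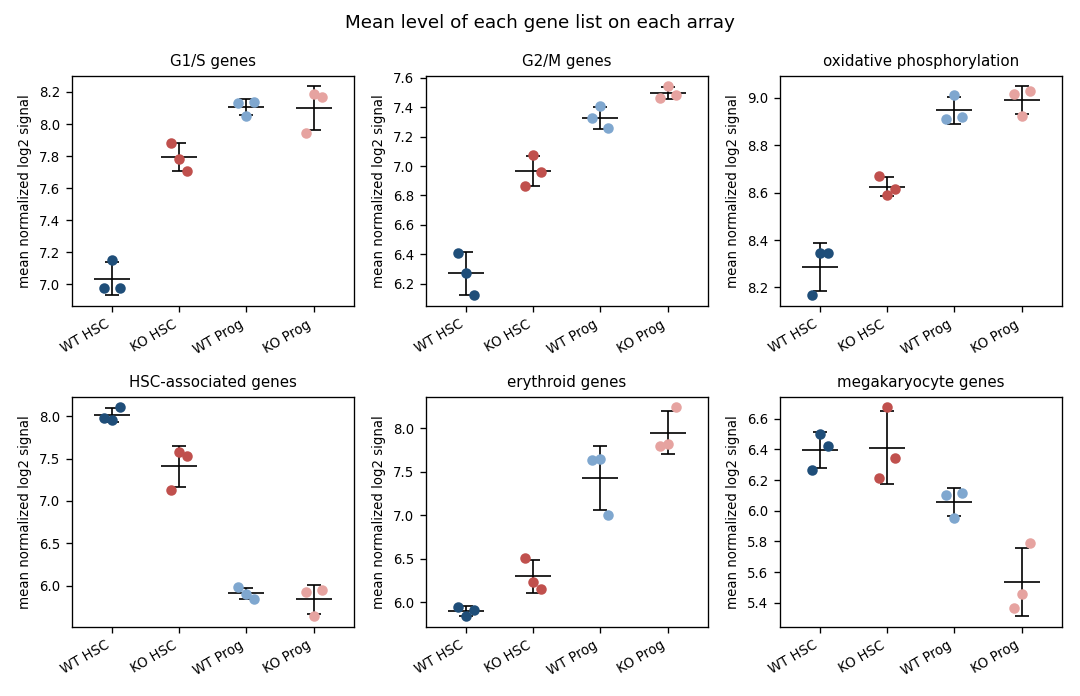
Mean normalized log2 signal of 6 gene lists (y axes, each with its own range) on each array of the 4 groups (x axes). Points are arrays, lines are group means and bars are SD (n = 3). The G1/S mean was 7.71 to 7.88 on the KO HSC arrays against 6.97 to 7.15 on the WT HSC arrays, and the HSC-associated mean was 7.13 to 7.57 against 7.95 to 8.10.

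Erythroid genes were higher for 20 of 26 members (mean 0.40, adjusted p = 0.00517, adjusted p = 0.363 with an estimated correlation), with none past the threshold over all genes and 2 when adjusted over the list alone. The globins Hbb-b1 and Hba-a1 gave 1.46 (adjusted p = 0.122) and 2.23 (0.176). Without KO HSC replicate 2, Hba-a1 passed (3.06, adjusted p = 0.0263), and Hbb-b1 passed with the trend and robust variance model (0.0153). Macrophage markers were higher for 6 of 8 (mean 0.83, adjusted p = 0.00517, adjusted p = 0.363 with an estimated correlation), with 1 member, Cd163, past the threshold either way and the iron exporter Slc40a1 at 1.29 (adjusted p = 0.401). Interferon response genes were lower for 19 of 26 (mean -0.34, adjusted p = 0.0477, adjusted p = 0.170 with an estimated correlation), with none past the threshold over all genes and 1 lower when adjusted over the list alone. Ifi44 gave -1.64 (adjusted p = 0.116) and Ifit3 -1.09 (0.396). Ifi44 passed without background correction (adjusted p = 0.0311) and with the authors' log2 values (0.0475). Without KO HSC replicate 1 the number of lists called went from 7 to 4, since erythroid genes (adjusted p = 0.0526), macrophage markers (0.0516) and interferon genes (0.0526) no longer met the threshold. The interferon call was also lost without WT HSC replicate 2 (0.115), WT HSC replicate 3 (0.0598), KO HSC replicate 2 (0.0906) and KO HSC replicate 3 (0.0849), and with fry (0.0592), median scaling (0.0652) and the Xist covariate (0.0847).

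Over all genes, 40 of 13841 passed the threshold, 22 higher and 18 lower in KO HSC. Among them, 11 carry only a clone or locus symbol. An unadjusted p under 0.05 was reached by 1420 genes, and the values of both groups did not overlap for 16.6% of genes, where chance gives 10%. The genes that rose most were led by Cd163, the macrophage scavenger receptor for haemoglobin, at 3.11 ± 0.54 (adjusted p = 0.0234, a second probe gave 1.35). Next came Cdca2, a chromatin-bound phosphatase regulator of mitosis (2.19), Bcl2a1d, of the anti-apoptotic A1 genes (2.18, at least 3.52-fold, uncertain since its paralogs are near-identical) and Tex30 (2.18). They were followed by Tyrobp, a signalling adaptor of myeloid and NK cell receptors (2.12), Litaf (2.12), Depdc1b (2.08), the small GTPase Rhoq (2.03, a second probe gave -0.34), Mthfd2, a mitochondrial folate enzyme (2.03, a second probe gave 0.31), and Endod1 (2.01). The genes that fell most were led by Chrnb1, an acetylcholine receptor subunit, at -2.76 ± 0.33 (adjusted p = 0.00577, a second probe gave -0.12). It was followed by Dock6 (-2.39), Gsap (-2.09) and Rprm, a p53-induced inhibitor of cell cycle progression (-2.04). Also lower were Gstt2 (-1.84, a second probe gave 0.25), Zfp933 (-1.82), Zfp711 (-1.80, at least 2.27-fold lower, a second probe gave 0.10), Trim30b (-1.68), the Slit receptor Robo1 (-1.65, at least 2.42-fold lower) and Ascc2 (-1.44, though 2 of its other probes gave 0.22 and 0.56). With quantile values without background correction, 22 genes were higher and 31 lower, and with median scaling 15 and 24. The count fell to 0 without KO HSC replicate 1, 5 without WT HSC replicate 1, 10 without WT HSC replicate 3, 19 without WT HSC replicate 2 and 0 in a fit of the HSC arrays alone. It was 14 with the description number as replicate block. Xist was high on 2 WT and 1 KO HSC arrays, and with its level as a covariate 23 genes passed, 22 of them among the 40.

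Dnmt3a, the DNA methyltransferase named in the series title, had a level of 7.57 ± 0.33 (SD) in KO HSC and 6.78 ± 0.20 in WT HSC. The log2 fold change of 0.79 ± 0.37 (SE) did not pass the threshold (adjusted p = 0.483). Each of the 3 KO arrays lay above each WT array, but 16.6% of all genes did not overlap between these groups in either direction. The Dnmt3a homologue Dnmt3b gave 0.61 and the methylcytosine dioxygenase Tet2 -0.40, neither past the threshold. Published miR-29 targets as a list had a mean of 0.25 with 22 of 37 members higher and 15 lower (adjusted p = 0.0957, 0.344 with an estimated correlation). Among the higher were Igf1 at 1.89 (adjusted p = 0.197) and Nasp at 1.00, and the targets Mcl1 and Cdk6 gave 0.05 and 0.55. All of these targets had a higher mean in KO HSC, so they do not stand for the 15 lower members. DNA methylation enzymes had a mean of 0.19 (adjusted p = 0.155), and collagens and extracellular matrix genes 0.37 (0.215). Of the remaining genes named in advance, Meis1 gave -0.84, Mecom -0.79 and Mpo 0.33, and of the gate antigens Kit gave -1.0 (adjusted p = 0.283), Ly6a, which encodes Sca-1, -0.73, Slamf1 0.82 (another probe gave -0.36) and Cd34 0.62. None passed. The other lists did not pass (adjusted p from 0.156 to 0.971). The mean log2 fold change was -0.07 for gate antigens, -0.12 for quiescence and cell cycle inhibitors, 0.08 for granulocyte and monocyte progenitor genes, 0.01 for megakaryocyte genes and 0.12 for lymphoid priming genes. It was 0.00 for mature B cell markers, -0.03 for T and NK cell markers, -0.08 for mature neutrophil markers, 0.35 for mast cell and basophil markers, and -0.20 for stromal and endothelial markers. It was 0.05 for ribosomal proteins, 0.17 for glycolysis, -0.06 for immediate early genes, -0.02 for heat shock and unfolded protein response genes and -0.04 for p53 targets and apoptosis genes.

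**Figure D2:**
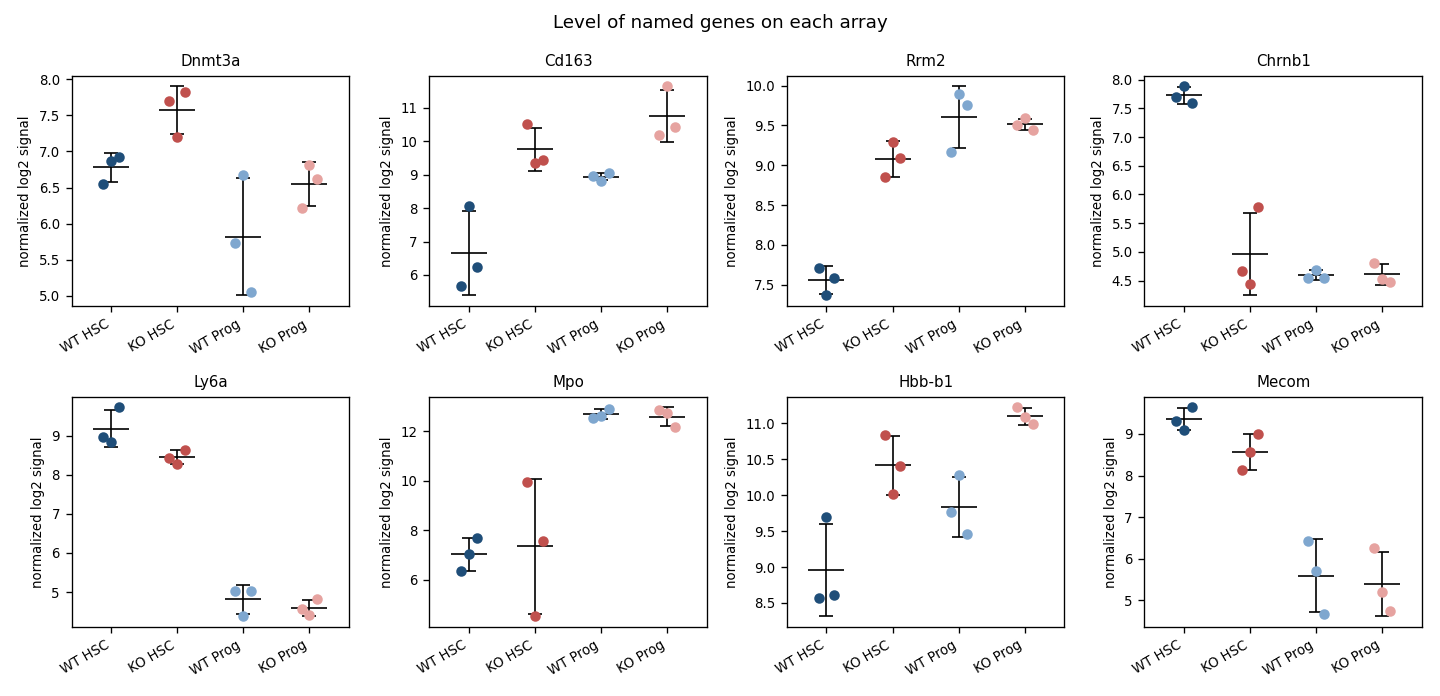
Normalized log2 signal (y axes, each with its own range) of 8 named genes on each array of the 4 groups (x axes). Points are arrays, lines are group means and bars are SD (n = 3). Dnmt3a lay at 7.20 to 7.82 on the KO HSC arrays and 6.55 to 6.92 on the WT HSC arrays, and Chrnb1 at 4.45 to 5.78 against 7.60 to 7.88.

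In committed progenitors, the same comparison gave a shift of lineage genes with camera at the preset correlation only, and no gene past the threshold. Erythroid genes were higher in KO for 22 of 26 members (mean log2 fold change 0.52, camera, adjusted p = 1.50e-05) and megakaryocyte genes lower for 12 of 17 (mean -0.52, adjusted p = 0.00155), both with adjusted p = 0.247 with an estimated correlation. Mature neutrophil markers were higher for 9 of 10 (mean 0.65, adjusted p = 0.000327, adjusted p = 0.247 with an estimated correlation) and macrophage markers for 8 of 8 (mean 0.97, adjusted p = 7.12e-05, adjusted p = 0.254 with an estimated correlation). Immediate early genes, induced within minutes of a stimulus, were lower for 16 of 18 (mean -0.83, adjusted p = 0.000327, adjusted p = 0.406 with an estimated correlation), and ribosomal protein genes for 43 of 63 (mean -0.16, adjusted p = 0.0315, adjusted p = 0.247 with an estimated correlation). None of the 6 lists passed with an estimated correlation.

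The haem enzyme Alas2 gave 1.72 ± 0.36 (SE, at least 2.35-fold, adjusted p = 0.249) and Hbb-b1 1.27, and 2 erythroid genes were higher when adjusted over the list alone. The platelet chemokine Pf4 gave -2.21 ± 0.62 (adjusted p = 0.441), with 3 megakaryocyte genes lower when adjusted over the list alone. The neutrophil genes Mmp9 and Ltf gave 1.63 and 0.76 (1 member over the list alone), the macrophage genes Axl and Cd163 2.01 (at least 2.89-fold) and 1.81 (2 members), the immediate early genes Jun and Ier3 -1.40 and -1.48 (no member), and the ribosomal genes Rps13 and Rps6 -0.84 and -0.82 (no member, a second Rps13 probe gave 0.35). Second probes of Ltf, Axl and Cd163 gave 0.31, 0.013 and 0.92. Macrophage markers were highest on KO replicate 2, where Axl lay at 7.99 and C1qb at 6.95 against 5.38 to 6.48 and 4.39 to 4.46 on the other KO arrays, and the list call was lost without that array (mean 0.41, adjusted p = 0.12). Immediate early genes were highest on WT replicate 3, where Fos lay at 9.58 against 4.45 and 4.68 on the other WT arrays, and without it their mean was -0.05 (adjusted p = 0.823). The erythroid mean was 0.308 (adjusted p = 0.0283) without WT replicate 3. The mean level of mature neutrophil markers was 8.399 and 8.415 on KO replicates 2 and 3. On KO replicate 1 it was 7.449, within the WT range of 7.266 to 7.573. The ribosomal call was lost without KO replicate 1 (adjusted p = 0.0843), KO replicate 2 (0.12), WT replicate 2 (0.139) and WT replicate 3 (0.109), and with median scaling (0.405) and the Xist covariate (0.0517).

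With limma, 0 of 13841 genes passed in committed progenitors. An unadjusted p under 0.05 was reached by 934 genes, the smallest adjusted p was 0.104, and groups did not overlap for 11.3% of genes, where chance gives 10%. Tests of all probes and of the trend and robust variance model each called 1. The genes with the smallest p whose groups did not overlap were, besides Alas2, the class II antigen gene H2-Aa (2.10), Plbd1 (2.22, at least 3.46-fold), Lrp1 (1.61, at least 2.32-fold) and Cdr2 (1.40). In the other direction they were Marcksl1 (-1.69, at least 2.31-fold lower), the cGMP-dependent kinase Prkg1 (-1.68, a second probe gave -0.47), Gng11 (-1.59, at least 1.77-fold lower) and the thrombin receptor F2rl3 (-1.32), with adjusted p from 0.104 to 0.249. Dnmt3a gave 0.73 ± 0.37 (adjusted p = 0.761), and Dnmt3b -0.09, Tet2 -0.27, Mcl1 0.26, Cdk6 -0.84, Mpo -0.11, Meis1 -0.04, Mecom -0.20, Kit -0.60, Slamf1 0.49 and Cd34 -0.84 did not pass. Other probes gave the opposite sign for Tet2 (0.04), Mpo (0.08), Meis1 (0.45), Mecom (0.46 and 0.01), Kit (0.53) and Slamf1 (-0.38). Ly6a was not above background in either group. Published miR-29 targets had a mean of 0.08 (adjusted p = 0.543), with 21 of 37 members higher and 16 lower. Among the higher were Igf1 at 1.96 (at least 2.96-fold) and Lpl at 1.67, neither past the threshold. All 3 KO arrays had low Xist, against 1 of 3 WT arrays with a high level.

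No gene's KO effect differed between HSC and committed progenitors in the test of the difference (0 of 13841 past the limma threshold, 979 with an unadjusted p under 0.05, smallest adjusted p = 0.295). The genes with the smallest p were Marcksl1, Ulbp1 (2.43, KO effect in HSC minus that in committed progenitors), Cdca2 (2.75), Gins1 (1.86) and the deaminase Ada (1.77), and in the other direction Chrnb1, Gsap, Spryd7 (-2.04), H2-Aa (-2.40) and Zfp711 (a second probe gave 0.29). No size is given for 4 of them, since their probes were detected on no array of at least 1 group: KO committed progenitors for Marcksl1, WT committed progenitors for Gsap, both groups of committed progenitors for Chrnb1, and all groups but WT HSC for Zfp711. Ulbp1 was detected on 1 of 3 WT HSC arrays and on 2 of 3 KO committed progenitor arrays, and H2-Aa on 2 of 3 WT committed progenitor arrays. Without KO HSC replicate 3, 3 genes passed, Chrnb1 among them (adjusted p = 0.00815). Of the 25 lists, 9 differed with camera, 1 with an estimated correlation and 3 with fry. The G1/S genes differed by 0.76 (adjusted p = 6.92e-08, 0.00508 with an estimated correlation). Across genes, which are not independent replicates, the KO effects in both populations correlated with r = 0.115, and 53.4% had the same sign. The correlation was 0.053 without KO committed progenitor replicate 3.

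The comparison of WT HSC with WT committed progenitors describes the difference between the populations. HSC-associated genes were higher in HSC for 41 of 44 members (mean log2 fold change 2.10, camera, adjusted p = 5.20e-25), 34 of them past the threshold over all genes and 37 when adjusted over the list alone. Hoxb5 gave 4.47 (at least 14.4-fold) and Procr, the endothelial protein C receptor, 4.37 (a second probe gave 1.27). Granulocyte and monocyte progenitor genes were lower in HSC (mean -2.37, adjusted p = 1.54e-14), 15 of 23 past the threshold and 18 over the list alone, with Ms4a3 at -4.80 (at least 23.1-fold lower) and Trem3 at -3.90. Erythroid genes (mean -1.53, adjusted p = 3.97e-10, 13 of 26 lower past the threshold, 19 over the list alone) were led by the blood group gene Rhd (-3.38) and the transcription factor Klf1 (-3.39), and mature neutrophil markers (mean -2.29, adjusted p = 1.56e-08, 6 of 10 lower past the threshold, 7 over the list alone) by S100a8 (-4.10) and Ltf (-2.95). G1/S genes (mean -1.07, adjusted p = 1.81e-09) were lower past the threshold for 14 of 29, 16 over the list alone, with Cdc6 at -2.44 and Rrm2 at -2.04. G2/M genes (mean -1.06, adjusted p = 1.81e-09) were lower past the threshold for 19 of 32, 21 over the list alone, with Birc5 at -2.43 and Tpx2 at -2.56, while 1, Kif23, was higher past it at 1.14 (other probes gave -0.87 and -0.71).

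Oxidative phosphorylation genes were lower in WT HSC (mean -0.66, adjusted p = 1.16e-09, 13 of 67 past the threshold, 16 over the list alone, Ndufs1 -1.88, Uqcrc1 -1.57), and interferon response genes higher (mean 0.90, adjusted p = 4.76e-05, 8 of 26, 10 over the list alone, Ifi44 3.42, Oasl2 3.79). Gate antigens were higher for 3 of 4 (mean 1.71, adjusted p = 0.0102, adjusted p = 0.0513 with an estimated correlation): Ly6a by 4.36 (at least 17.0-fold), Slamf1 by 2.28 (at least 3.35-fold) and Kit by 1.06, while Cd34 gave -0.87 (adjusted p = 0.167). Sca-1, Slam1 and CD34 were part of the HSC gate, so this list is no independent finding. Both populations were sorted as positive for c-Kit, so the gate did not set them apart by Kit. Mast cell and basophil markers were lower (mean -1.80, adjusted p = 0.0117, adjusted p = 0.159 with an estimated correlation), with 3 of 8 lower and 1 higher past the threshold. The other 8 lists named here passed with an estimated correlation.

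Over all genes, 2260 passed in WT, 1185 higher and 1075 lower in HSC, and 498 carry only a clone or locus symbol. Higher in HSC were Afdn, an adherens junction protein (4.97), Spaca6 (4.92, at least 20.2-fold), the proteoglycan Bgn (4.79), Matn4 (4.33), Cadps2 (4.18, at least 12.1-fold), the sulfotransferase Sult1a1 (4.12) and Socs2, a suppressor of cytokine signalling (4.07, at least 12-fold). Other probes gave 0.82 and 0.21 for Afdn and 0.39 for Socs2. Lower were the histamine-forming enzyme Hdc (-6.52, a second probe gave -1.26), the granule proteins Ctsg (-6.01, at least 52.0-fold), Mpo (-5.67) and Elane (-4.60). Next came the eosinophil granule genes Prg2 (-5.32) and Epx (-4.17, at least 14.1-fold), Chdh (-4.61, at least 17.6-fold), Cldn15 (-4.55, at least 19.9-fold) and the basophil protease Mcpt8 (-4.14, at least 13.4-fold). The HSC regulators Mecom (3.76) and Meis1 (2.54) were higher, and Dnmt3a (0.96, adjusted p = 0.0902), Dnmt3b (0.17), Tet2 (-0.12, a second probe gave 1.33), Mcl1 (0.66) and Cdk6 (-1.23) did not pass. Dnmt3a passed with median scaling (1.27, adjusted p = 0.0471) and without WT committed progenitor replicate 2 (1.39, adjusted p = 0.0221), and Mcl1 without background correction (0.58, adjusted p = 0.0344). With median scaling the median log2 fold change of all genes lay at 0.226 in this comparison and 0.252 in KO, against 0.0151 and 0.0115 in the values used, and 1732 genes were higher and 518 lower here. The count was 1466 without WT HSC replicate 1, 1466 without WT HSC replicate 3 and 1439 without WT committed progenitor replicate 2, and 16 instead of 10 lists were called without WT committed progenitor replicate 1.

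In KO, 1551 genes differed between HSC and committed progenitors, 812 higher and 739 lower in HSC, 307 of them with only a clone or locus symbol. HSC-associated genes were higher in KO HSC (mean 1.57, camera, adjusted p = 5.41e-18), 25 of 44 past the threshold and 29 over the list alone. Granulocyte and monocyte progenitor genes were lower (mean -2.23, adjusted p = 1.84e-16), 16 of 23 past the threshold and 17 over the list alone, with Trem3 at -3.68 (at least 9.29-fold lower). Erythroid genes were lower (mean -1.65, adjusted p = 8.97e-14), 17 of 26 and 18 over the list alone, with Rhd at -3.53. All 10 mature neutrophil markers were lower (mean -3.03, adjusted p = 8.36e-14), among them Ltf. Interferon response genes were higher (mean 0.75, adjusted p = 0.000207), 6 of 26 and 8 over the list alone, with Ifi44 at 3.17 and Gbp2 at 2.26 (at least 3.43-fold). Gate antigens were higher (mean 1.93, adjusted p = 0.000558), 2 of 4 past the threshold, and as in WT this list is no independent finding. These 6 lists also passed with an estimated correlation. Another 8 lists were called by camera and lost the call with an estimated correlation. The members counted as higher or lower in these 8 lists are those past the threshold. G1/S genes had a mean of -0.31 (adjusted p = 0.0402, and adjusted p = 0.093 with an estimated correlation) with 3 of 29 lower, among them Cdc6 (-1.65) and Slbp (-1.89), and their mean was 0.00 under median scaling. G2/M genes had a mean of -0.53 (adjusted p = 0.00101, and adjusted p = 0.0624 with an estimated correlation) with 9 of 32 lower and 10 over the list alone. Among them were Birc5 (-1.24), of which another probe gave 0.26, and Nusap1 (-1.40), of which other probes gave 0.20 and 0.77. Oxidative phosphorylation genes had a mean of -0.37 (adjusted p = 0.00058, and adjusted p = 0.0696 with an estimated correlation) with 4 of 67 lower, among them Uqcr11 (-1.04). Megakaryocyte genes had a mean of 0.87 (adjusted p = 0.00185, and adjusted p = 0.0936 with an estimated correlation) with 3 of 17 higher, 4 over the list alone, among them the adhesion molecule Selp (3.07). Quiescence and cell cycle inhibitor genes had a mean of 0.62 (adjusted p = 0.00496, and adjusted p = 0.093 with an estimated correlation) with 6 of 20 higher, 8 over the list alone, among them Ndn (2.67, at least 4.02-fold) and Txnip (1.62). Published miR-29 targets had a mean of 0.41 (adjusted p = 0.0144, and adjusted p = 0.0967 with an estimated correlation) with 6 of 37 higher and 2 lower, among them Col4a1 (2.61) and Mycn (2.03, at least 2.58-fold). Macrophage markers had a mean of -1.01 (adjusted p = 0.0105, and adjusted p = 0.263 with an estimated correlation) with 2 of 8 lower. Heat shock and unfolded protein response genes had a mean of -0.35 (adjusted p = 0.0452, and adjusted p = 0.218 with an estimated correlation) with no member past the threshold, and their mean was -0.08 (adjusted p = 0.0632) under median scaling.

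Highest in KO HSC over KO committed progenitors were Socs2 (5.05), the immunoglobulin genes Igkc (4.48) and Igh-VJ558 (4.02), Bgn (4.27), Afdn (4.21), Unc45b (4.03, at least 9.51-fold), Ly6a (3.86, at least 9.36-fold), the endothelial adhesion molecule Esam (3.79, at least 11.4-fold) and Tmem176a (3.77, at least 9.57-fold). Other probes gave 0.24 for Socs2, 1.25 and 0.22 for Afdn and 0.64 for Tmem176a. Lowest were Camp (-5.31, at least 37.1-fold), Mpo (-5.24), Ctsg (-4.74), S100a8 (-4.67), Hdc (-4.63), Chil3 (-4.57, at least 17.0-fold), Spon2 (-4.52, at least 19.7-fold), F10 (-4.46, at least 16.6-fold), Cldn15 (-4.43) and Sphk1 (-4.34). Second probes gave -0.83 for Hdc and -0.94 for Sphk1. Mecom (3.17), Slamf1 (2.61) and Meis1 (1.75) were higher, and Dnmt3a (1.02, adjusted p = 0.0886), Dnmt3b (0.86), Tet2 (-0.25, a second probe gave 0.95), Mcl1 (0.46), Cdk6 (0.16), Kit (0.66) and Cd34 (0.59) did not pass. Dnmt3a passed with median scaling (1.5, adjusted p = 0.026) and without background correction (0.61, adjusted p = 0.0378). Median scaling gave 1446 higher and 305 lower. The count was 1022 without KO HSC replicate 2 and 880 in a fit of the KO arrays alone. The call was lost for G1/S genes without KO HSC replicate 3 (adjusted p = 0.0862), KO committed progenitor replicate 2 (0.0791) or 3 (0.0835), for macrophage markers without KO committed progenitor replicate 2 (0.265), and for heat shock genes without KO HSC replicate 1 (0.0692) or 3 (0.0521) or KO committed progenitor replicate 2 (0.0791) or 3 (0.0835). It was also lost for macrophage markers with fry (0.0763) and for heat shock genes with the Xist covariate (0.0823).

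Both comparisons of populations shared 485 genes higher in HSC, where independent lists would share 69.5, and 448 lower (57.4 for independent lists). Opposite directions were called for 2 genes, and the fold changes correlated across genes with r = 0.726. The genes that changed in KO HSC were set against the population difference in WT. Of the 22 genes that rose in KO HSC, 19 were lower in WT HSC than in WT committed progenitors (1.71 for independent lists), and of the 18 that fell, 17 were higher (1.54), while 0 went the other way. Both comparisons use the WT HSC arrays, so part of this overlap may come from them. Across all genes the KO effect in HSC correlated with the committed progenitor minus HSC difference in WT with r = 0.558 and a covariance of 0.246, against a mean r of 0.211 and a mean covariance of 0.0828 (highest of 100 simulations 0.232 and 0.0920) with simulated unchanged KO arrays. Genes varied independently in these simulations, so their narrow range does not cover noise that arrays share across genes. On an axis from WT HSC (0) to WT committed progenitors (1), with each WT array placed by the others and a measure chosen after seeing the data, the 3 KO HSC arrays lay at 0.337 ± 0.0512 (SD) and the WT HSC arrays at 0.129 ± 0.0339, without overlap (exact two-sided permutation test, p = 0.1, the smallest this design allows). KO committed progenitors lay at 0.945 ± 0.0364 and WT at 0.869 ± 0.0125 (exact permutation p = 0.1). Simulated unchanged arrays of either genotype lay at a mean of 0.122 for HSC and 0.877 for committed progenitors, not at 0 and 1.

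**Figure D3:**
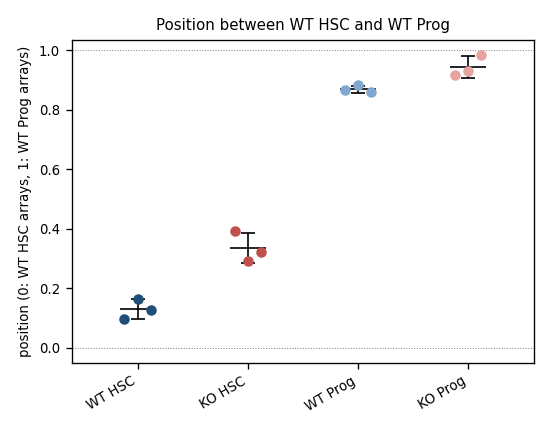
Position of each array (y axis, without unit) between the WT HSC arrays (0) and the WT committed progenitor arrays (1), by group (x axis). Points are arrays, lines are group means and bars are SD (n = 3). The KO HSC arrays lay at 0.293 to 0.393 and the WT HSC arrays at 0.0971 to 0.165. Simulated unchanged arrays lay at a mean of 0.122 for HSC and 0.877 for committed progenitors.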

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

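The tests of cell carry-over, of the sort gate, of single arrays and of a smaller share of a cell type were chosen only after the results they bear on had been seen. The test of scaling and the regroupings of arrays were set before.

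In 9 gene lists the KO effect in HSC differed from that in committed progenitors by a test of the difference (camera, values are KO effect in HSC minus that in committed progenitors, log2). The G1/S genes differed by 0.763 (adjusted p = 6.92e-08, and adjusted p = 0.00508 with an estimated correlation), the only list that kept its call with an estimated correlation. The G2/M genes differed by 0.532 (adjusted p = 6.18e-05, and adjusted p = 0.0662 with an estimated correlation). HSC-associated genes differed by -0.528 (adjusted p = 8.29e-05, and adjusted p = 0.177 with an estimated correlation), with a KO effect of -0.60 in HSC and -0.07 in committed progenitors. Oxidative phosphorylation genes differed by 0.294 (adjusted p = 0.000873, and adjusted p = 0.177 with an estimated correlation). Mature neutrophil markers differed by -0.737 (adjusted p = 0.00439, and adjusted p = 0.318 with an estimated correlation), with KO effects of -0.08 and 0.65. Immediate early genes differed by 0.765 (adjusted p = 0.0149, and adjusted p = 0.588 with an estimated correlation), but their KO effect in committed progenitors was -0.05 without WT replicate 3, close to the -0.06 in HSC. Megakaryocyte genes differed by 0.533 (adjusted p = 0.0352, and adjusted p = 0.374 with an estimated correlation), with KO effects of 0.01 and -0.52. Ribosomal proteins differed by 0.210 (adjusted p = 0.0352, and adjusted p = 0.189 with an estimated correlation) and glycolysis genes by 0.367 (adjusted p = 0.0352, and adjusted p = 0.378 with an estimated correlation).

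The first pattern weighed is the rise of cell cycle genes with the fall of HSC-associated genes in KO HSC. Committed progenitors carried over into the KO HSC sorts would bring their granulocyte and monocyte transcripts too. The cell cycle genes would need a median share of 42.4% to 46.9% on the 3 KO HSC arrays. The highest median over these arrays was 3.80% for 15 granulocyte and monocyte genes (upper quartile 9.75%), 10.1% for 13 erythroid genes (upper quartile 25.7%) and -2.62% for 6 neutrophil genes. The 3.80% came from KO HSC replicate 1, against -1.61% and -0.408% on replicates 2 and 3. On replicate 1 Mpo lay at 9.95, against 6.33 to 7.69 in WT HSC, and without this array no gene passed in KO against WT HSC. The upper quartile of the granulocyte and monocyte genes lay below the lowest lower quartile of the cell cycle genes (17.4%), which argues against carry-over of mixed committed progenitors as the whole source. The erythroid genes alone do not exclude it, since their quartiles overlapped those of the cell cycle genes on KO replicate 2. Scaling and background correction are argued against as the whole source, since the 3 lists kept their direction under all 3 other sets of values, with a largest adjusted p of 2.73e-09. The HSC gate, negative for CD34 and positive for Slam1, is meant to remove the other Sca-1 and c-Kit positive progenitors. More of them in the gate still cannot be told apart from a change within HSC, since Slamf1 gave 0.82 (another probe -0.36), Cd34 0.623 (SE 0.41) and Flt3 -0.671 (SE 0.551), none past the threshold (adjusted p = 0.498, 0.679 and 0.763), and a second Flt3 probe gave 0.468. A larger share of cycling cells within the HSC of KO mice was not tested apart from this.

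The second pattern is the opposite movement of lineage lists in KO committed progenitors. All 4 lists, erythroid, megakaryocyte, neutrophil and immediate early, stayed called by camera at the preset correlation whichever KO array was left out. No single KO array therefore carried these calls, which says nothing about dependence on a WT array. The megakaryocyte list was called narrowly without KO replicate 1 (camera, adjusted p = 0.042). Without KO replicate 2 the same held for the neutrophil and immediate early lists (0.0413 and 0.0443). With all arrays none of the 4 passed with an estimated correlation (adjusted p = 0.247 for the first 3 and 0.406 for immediate early genes) or with fry (0.244, 0.142, 0.244 and 0.349). The erythroid mean did depend on WT replicate 3, without which it was 0.308 (adjusted p = 0.0283). The macrophage shift may rest on KO replicate 2, since its adjusted p was 0.12 without that array. The immediate early shift depended on WT replicate 3, where the list lay at 8.605 against 6.277 and 6.258 on WT replicates 1 and 2. Without WT replicate 3 the mean shift was -0.05 (camera, adjusted p = 0.823). From their WT means, the erythroid list shifted by 1.04 more than the megakaryocyte list. The difference was 0.986 to 1.08 on the 3 KO arrays (SD 0.0486), with an SD of 0.431 over the WT arrays. A smaller share of a cell type outside these lineages, with all others rising alike, would not give opposite signs. The opposite signs are the pattern itself and were known beforehand, so they are no separate test of that explanation. A smaller share of megakaryocytic cells would give opposite signs, so it is not excluded. A change of the erythroid or megakaryocyte share with genotype was not tested against a change within these cells.

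Splits of the 6 arrays of a comparison into 3 and 3 number 10, the real one included, too few for a share under 0.05. KO against WT in HSC gave 40 genes and 7 lists in the real split (1 of 10 splits gave as many of either), where the highest of the other splits gave 1 gene and 4 lists. In committed progenitors the real split gave 0 genes (all 10 splits gave as many, the highest other 2) and 6 lists (2 of 10, the highest other 6). HSC against committed progenitors gave 2260 genes in WT (1 of 10, highest other 0) and 1551 in KO (1 of 10, highest other 1), with 10 lists in WT (6 of 10, highest other 11) and 14 in KO (1 of 10, highest other 7). For the test of the difference, the real grouping gave 0 genes, which each of 100 genotype regroupings reaches by necessity (the highest gave 4), so these say nothing about chance. The correlation of both KO effects (0.115) was reached in absolute value by 2 of 100 regroupings, the real one and the same grouping with the labels of 1 population swapped (-0.115). With all arrays this argues against chance regrouping, but without KO committed progenitor replicate 3 the correlation was 0.053, within the range of the other regroupings, so its size depends on that array.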

How the results depend on the processing

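Of the values recomputed under other settings, those that moved a main result or turned a direction follow, and the cause was not tested for any of them. For KO against WT in HSC, 40 genes became 0 in a fit of only the HSC arrays, 14 with the description number as replicate block and 23 with the Xist level as covariate, a setting chosen after the data were seen. Leaving out 1 array gave 0 (without KO HSC replicate 1) to 43 (without KO HSC replicate 2), so that no named call in this comparison held in every refit. In committed progenitors, 0 genes became 1 with all detected probes and 1 with the trend and robust variance model. HSC against committed progenitors gave 1439 (without WT Prog replicate 2) to 1705 (without WT HSC replicate 2) genes in WT. In KO it gave 880 in a fit of only the KO arrays and 1022 (without KO HSC replicate 2) to 1219 (without KO HSC replicate 1) when 1 array was left out. The test of the difference gave 0 (without WT HSC replicate 1) to 3 (without KO HSC replicate 3).

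The lists called in KO against WT HSC were 4 with an estimated correlation, 4 with fry and 4 (without KO HSC replicate 1) to 7 (without WT HSC replicate 1) when 1 array was left out. In committed progenitors they were 0 with an estimated correlation and 0 with fry. HSC against committed progenitors gave 19 lists with fry in WT and 10 (without WT HSC replicate 3) to 16 (without WT Prog replicate 1) when 1 array was left out, and 6 with an estimated correlation in KO. The correlation of both KO effects was 0.142 without background correction and 0.053 (without KO Prog replicate 3) to 0.137 (without KO Prog replicate 1) when 1 array was left out. The correlation of the KO effect in HSC with the committed progenitor minus HSC difference in WT was 0.481 (without KO HSC replicate 1) to 0.597 (without WT HSC replicate 2).

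Directions turned only for genes that had not passed and for 1 list. Without background correction the list means were smaller with their directions kept, such as 0.46 for G1/S genes in KO against WT in HSC. Median scaling gave Tet2 at 0.17 in HSC against committed progenitors of WT and 0.21 of KO, and the G1/S genes at 0.00 in KO. The Xist covariate gave Mpo at 0.13 and Meis1 at 0.01 for KO against WT in committed progenitors. Leaving out 1 array gave, for KO against WT in HSC, Mcl1 from -0.05 to 0.17, Mpo from -0.98 to 1.74 and Chaf1b from -0.39 to 0.14. In committed progenitors it gave Dnmt3b from -0.47 to 0.10, Mpo from -0.25 to 0.11, Meis1 from -0.46 to 0.39 and Mecom from -0.66 to 0.22. For HSC against committed progenitors it gave Dnmt3b from -0.22 to 0.42 and Tet2 from -0.35 to 0.03 in WT, and Cdk6 from -0.52 to 0.60 in KO. Arrays that share a description number correlated in their deviations at -0.064 to 0.0262 and those that share a title number at -0.0206 to 0.0111. The labels do not say what either number stands for, so neither was a block in the fit reported, and the block of 14 genes above is an alternative only.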

Other observations

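Every test in this part was chosen after the data were seen, except the regrouping test of the genes of chromosome 6. Immunoglobulin, granule and sex-linked transcripts differed between single arrays of a group. Igkc, an immunoglobulin light chain gene, lay at 8.97 to 11.4 on 5 of the 6 HSC arrays and at 5.96 on WT HSC replicate 1, against 5.54 to 6.35 in committed progenitors. The heavy chain gene Igh-VJ558 was at 4.38 on that same array and at 9.44 to 11.5 on the other 5 HSC arrays. Mpo, the granule peroxidase, lay at 9.95 on KO HSC replicate 1 and 4.52 on KO HSC replicate 2, against 6.33 to 7.69 in WT HSC.

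The X-inactivation RNA Xist and the Y-linked gene Eif2s3y were high on different arrays. Eif2s3y lay at 4.51 to 4.59 on the 4 arrays with Xist at 9.23 to 10, and at 7.33 to 9.21 on the other 8. The probe of a second Y-linked gene, Ddx3y, lay at 9.7 to 11.4 on all 12 arrays and did not separate them. The 3 pairs of arrays that share a title number across populations were alike in Xist and Eif2s3y, with Xist at 9.80 and 9.27, 4.74 and 5.44, and 5.57 and 4.64, although the deviations of these pairs from their group means correlated at only -0.0206 to 0.0111 across genes. Arrays with high Xist and low Eif2s3y were spread unevenly over the genotypes. A possible difference of sex was not separated from genotype, except in part by the Xist covariate.

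Genes that carry only a clone or locus symbol, 22.5% of those tested, leaned toward HSC in WT: 378 were higher and 120 lower in HSC, against 807 and 955 of the other genes, and their median log2 fold change was 0.241 against -0.0518. In KO the medians were 0.205 and -0.0456. These genes were also dimmer, with a mean level of 6.17 against 6.63. WT HSC arrays detected more probes than WT committed progenitor arrays (means of 40% and 34.4%), and whether this accounts for the lean was not tested.

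Averaged over both populations, the KO effect passed the threshold for 4 genes with limma: Bcl2a1d, Cd163, Igf2bp3 and a locus symbol. These were looked up after their values were seen. Igf2bp3, an RNA-binding protein of fetal HSC, gave -1.21 (adjusted p = 0.0494), with -1.22 in HSC and -1.21 in committed progenitors, and Cd163 gave 2.46 (adjusted p = 0.0430). A hypothesis was that genes near the Mir29a locus on chromosome 6 differ because a segment of another strain may surround it. Of the 50 genes with the smallest p for the KO effect averaged over both populations, 5 lay on chromosome 6, where 2.55 were expected, but 11 of 100 genotype regroupings gave as many, the highest 7. These genes lay a median of 284 genes from Mir29a, against 168 for all chromosome 6 genes tested (permutation p = 0.913, one-sided), but Gng11 and Igf2bp3 lay 50 and 63 genes away. The 40 genes nearest to Mir29a had a median absolute KO effect of 0.237 against 0.214 for all genes. With 5 genes, such a segment is neither shown nor excluded.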
